A study of Mus musculus with 7 samples.

How the data were processed

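The data were 7 2-colour Agilent arrays, 1 for each of 7 mouse colon epithelial cell lines, with genomic DNA of the line labelled with Cy3 (green) and mouse liver DNA labelled with Cy5 (red), per the labels' protocols. Lines were grouped by the sex in the labels, 4 female and 3 male, and named by the codes in their titles. Each line is 1 sample. Which lines came from separate animals, and whether M2C and M2K share one, is not given in the sources used here, so p-values concern these lines only. Rotation p-values measure placement along the genome. Those of limma draw on a spread shared over all bins or genes, besides the spread between lines. The p with a number in the labels was read as the passage.

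Per the file headers, spots were read with Feature Extraction 10.5.1.1, with a spatial and multiplicative detrending of the background-subtracted intensity, a linear dye normalization, and probe positions on mouse build mm9. The deposited scanner files hold spot intensity values, and a log10 ratio of red over green that the authors' software computed from them; the log10 ratio was used as a check. It equalled the ratio of the processed signals within 0.001 in at least 99.8% of spots of each array. The value table deposited with the series holds log2 values of green over red that step between runs of equal values, and its columns set against the scanner values had a slope near 1, which settles scale and direction. Its column medians were 0.02 for F1K, -0.04 for F2K, -0.14 for F3K, -0.01 for F4K, 0.03 for M1K and 0.05 for M2C and M2K; how it was centred stays unknown, and the segmentation method behind it is not given in the sources used here.

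The ratio of each spot was taken as log2 of the processed green over the processed red intensity, so that a gain in the line is positive. Of 243301 spots, 5099 control spots were left out, and so were spots flagged as outliers, 197 to 529 per array. Spots of 1 probe were averaged, which concerned 1400 probes. Each array was centred on the median of its autosomal probes. Probes without a position, 1038, or on unplaced sequence, 344, were left out. Between 0.129% and 0.534% of spots per array were not well above background or saturated, and these were kept.

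Each chromosome was divided into segments by penalised least squares (optimal partitioning, penalty 10 times the noise variance times the log of the number of probes, at least 5 probes per segment), after single-probe outliers had been clipped at 3 SD of a running median over 9 probes. Segments were called gained at a log2 ratio of 0.2 and lost at -0.2. Autosomes were divided into 2392 bins of 1 Mb with at least 10 probes. Recurrence was tested by rotating the calls of each line along the autosomes by an independent offset, with 10000 draws, one-sided, and by the maximum over bins for single bins. Chromosome medians were tested with an exact sign-flip test and Benjamini-Hochberg adjustment over 19 autosomes. limma 3.58.1 in R 4.3.3 fitted bins and genes with the mean over lines tested against 0, and female minus male lines; adjusted p-values are Benjamini-Hochberg values from limma. The X and Y medians were compared by exact permutation over 35 splits.

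A gene's value is the median log2 ratio of the probes within 100 kb of the span of the probes annotated to it. Names are those of the array, which gives no exon or intron positions; 25580 gene names were on it, and 16873 symbols were matched by symbol or by an unambiguous older name to the RefSeq gene table of assembly GRCm38.p6, used for names only. After 6 genes on several chromosomes and 619 on X or Y were left out, 16248 genes were tested. The 23 gene lists were fixed before the data were examined; 9 of their genes were not found by name on the array, and 2 on X were left out of the autosomal tests. A list's value is the mean over lines of the median of its genes, tested two-sided by rotating the positions of all genes by 1 common offset, with 10000 draws and Benjamini-Hochberg adjustment over the 23 lists. Focal events are segments of at most 5 Mb with a mean log2 ratio of at least 1 or at most -1, leaving out Y.

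Named genes followed a rule fixed before the data were examined: a few genes in any case, among them Apc, Trp53, Smad4, Myc and Cdkn2a; genes of the lists gained in at least 3 or lost in at least 3 lines, or within a segment beyond 1 or -1 in any line, up to 30 by the absolute mean; for a recurrent region without such a gene, the annotated gene at its strongest bin; and for up to 10 focal segments, the list genes inside or else the gene at the middle probe. In all 48 genes met it, some of which are not reported here, and 137 list genes met the criteria for the 30 places. Other members of a list named beside its count were chosen by passing the test, after their values were seen.

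The alternatives fixed before the data were examined were centring on the peak of the bin values, normexp background correction with an offset of 50, the deposited value table, a filter to probes well above background and not saturated on all arrays, other thresholds for calls, segments, bins, focal events and recurrence, a gene's own probes, other summaries of lists and chromosomes, scan day as a block, M2C and M2K averaged, and leaving out each line. The normexp setting took the raw mean signals, without the software's detrending. Arrays were scanned on 4 days and 2 scanners. A correction for GC content, 2 further centrings and values within a scan day, with passage against scan day as a block, were added after the data were seen.

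The steps were tested on simulated data. At the noise of the quietest array 20 of 20 focal segments shifted by 1 were found, and at that of the noisiest, F3K, 11 of 20: 0 of 5 with 10 probes, 1 of 5 with 20 and 5 of 5 with 50. Without recurrence, 7% of 200 simulated data sets had a rotation p under 0.05, and without an effect 5.4% of 1000 simulated lists did. Blocks in the recurrence simulations were placed without regard to chromosomes, so the 7% does not cover calls of whole chromosomes. Simulated lists had their genes in several clusters at random places, and the simulated values were shared over short blocks of genes. The 5.4% therefore does not cover lists that lie on 1 chromosome, nor shifts of whole chromosomes. A block of 300 bins shared by 6 lines gave a permutation p of 0.007 in 1 simulated data set with 3 other altered blocks per line, and 0.130 in another with 6. A block of 120 bins with 6 other blocks per line gave a permutation p of 0.152, so that shared blocks can be missed. In 2392 simulated bins limma recovered 51.5% of 200 bins shifted by 0.3 in all lines and 98.5% of those shifted by 0.6; for female against male lines it recovered 0% and 46.5%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 was used for the other steps, and matplotlib 3.10.9 for the plots.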

Results

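Genomic DNA of 7 mouse colon epithelial cell lines was compared with normal mouse liver DNA on 2-colour oligonucleotide arrays (array comparative genomic hybridisation, which measures copy number as the ratio of test to reference signal at each probe). The lines came from C57BL/6 mice, were grown in reduced serum and had become immortal and transformed spontaneously in culture, according to the labels. There were 4 lines labelled female (F1K, F2K, F3K and F4K) and 3 labelled male (M1K, M2C and M2K), taken at passage 48 to 65. Each line had 1 array, so a value of a single line has no replicate error, and the number of arrays limits the precision. An array carried 235402 measured probes, 221455 of them on autosomes, and positions are those of mouse build mm9. The spread of differences between neighbouring probes, as the scanner software gave it, ran from 0.132 in M1K to 0.421 in F3K. The stated aim was to set the changes in these lines against those of human colon cancer.

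The reference was labelled male for every array, but the reference signal of the X chromosome went with the sex of the line. On the 4 arrays of female lines the X signal of the reference was 97.7% to 99.2% of its autosomal signal, and its Y signal was 0.732% to 7.84%. On the 3 arrays of male lines the X signal of the reference was 50.8% to 53.7% and its Y signal 48.4% to 52.5%. These values argue against male reference DNA on the 4 arrays of female lines. The DNA is called the reference labelled male below, after its label, and ratios on X and Y are given with this limit.

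Every line had lost and gained large parts of its genome. On average 26.1% ± 6.25 (SD, n = 7) of the autosomal genome was gained and 25.4% ± 11.5 (SD, n = 7) was lost, relative to each line's own median. F1K had the most altered genome, with 38.5% gained and 33.8% lost, and F4K the least, with 20.9% gained and 11.9% lost. M1K had the highest share lost, 40.1%, and F2K the lowest, 10.7%. The peak of the bin values lay above the call threshold of 0.2 in F1K, at 0.25, and in M2K, at 0.205. It lay below -0.2 in M1K, at -0.325, and in M2C, at -0.24. The commonest level of these lines could thus itself be called altered, so the shares and ranks of single lines depend on the centring. The autosomes fell into 48 segments of equal copy number in F1K and 85 in M2K, with 62.1 ± 14.9 (SD, n = 7) on average. With each array centred on the peak of its bin values, 35.3% was gained and 17.8% lost, and with normexp background correction 13.9% and 9.01%. The offset used with normexp compresses ratios, so calls at a fixed threshold can become fewer by construction.

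The same regions were altered in several lines. Distal chromosome 15 was gained in all 7 lines over 30 bins of 1 Mb, between 72000001 and 104000000, with a mean log2 ratio of 0.39 ± 0.17 (SD over lines, n = 7). Distal chromosome 4 was lost in all 7 lines over 24 bins, between 132000001 and 156000000, with a mean of -0.65 ± 0.19 (SD over lines, n = 7). Both rest on 1 line near the call threshold of 0.2: F4K was the weakest in the 30 gained bins, at a median of 0.20, and M2C in the 24 lost bins, at -0.22. At a call threshold of 0.3, 0 bins were gained and 0 lost in all 7 lines, and at 0.15 90 were gained and 35 lost. With peak centring 2 were gained and 0 lost, and with normexp 0 and 2. With centrings chosen after the data were seen, 0 were gained and 35 lost with chromosomes 2, 3, 5 and 7, and 3 gained and 24 lost with the chromosomes without recurrent bins. In the authors' deposited value table the lost bins numbered 11. Bins gained in at least 4 lines covered all of chromosomes 15 and 19, the 69 bins from 61000001 to 130000000 of chromosome 10, and parts of chromosomes 1, 6 and 11. Bins lost in at least 4 lines covered all of chromosomes 8 and 9, 88.2% of the bins of chromosome 4, and parts of chromosomes 12, 13 and 16.

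In numbers, 441 of 2392 bins were gained in at least 4 lines, against a median of 186.5 when each line's profile was rotated along the genome on its own (one-sided permutation p = 0.0005). For losses the count was 518 against a median of 156 (one-sided permutation p = 0.0001, the smallest the draws can give). The rotation moves calls across chromosome ends, while many calls covered whole chromosomes. It does not model lines that change whole chromosomes independently, so the rotation p-values for bins may be too small. Corrected for the maximum over bins, a bin gained in 7 lines had a permutation p of 0.0184 and a bin lost in 7 lines one of 0.0069. Bins shared by 6 lines did not pass, at a permutation p of 0.259 for gains and 0.148 for losses. At a call threshold of 0.15 bins in 7 lines did not pass (permutation p = 0.114 for gains and 0.124 for losses). With centring on the peak of the bin values, 876 bins were gained and 34 lost in at least 4 lines, and the losses no longer passed (permutation p = 0.0684). With normexp 49 were gained and 36 lost (permutation p = 0.0396 and 0.0076). A call threshold of 0.15 gave 824 gained and 913 lost bins, one of 0.3 gave 233 and 116, and with M2C and M2K averaged 277 were lost. With centring on the chromosomes without recurrent bins, 313 were lost. Bins gained in at least 4 lines numbered 220 without F1K, 271 without F2K and 274 without F4K; bins lost numbered 150 without M1K, 213 without F1K, 276 without M2C and 290 without F3K. With a line left out the threshold stayed at 4 lines, so these counts can only fall.

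**Figure D1:**
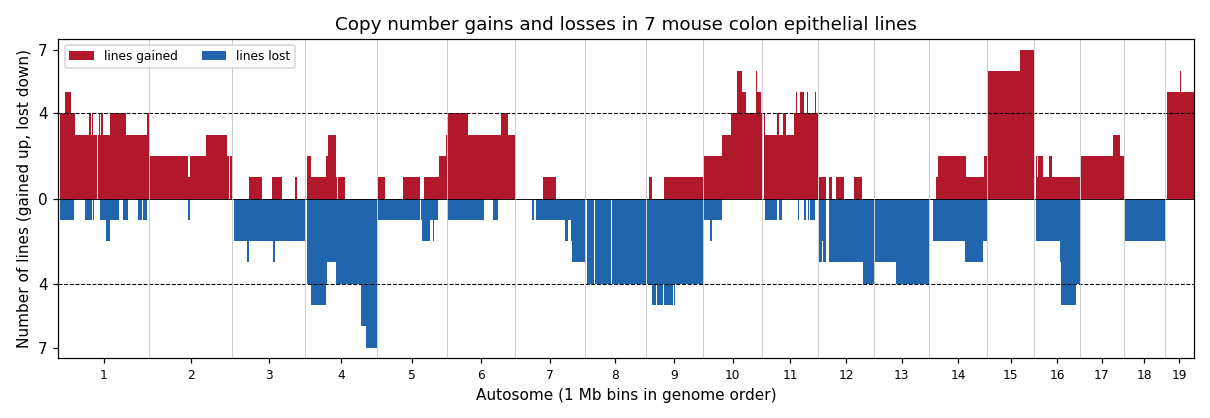
Number of lines (of 7) called gained, drawn upward in red, or lost, drawn downward in blue, in each 1 Mb autosomal bin in genome order; dashed lines mark 4 lines. Distal chromosome 15 reaches 7 lines gained and distal chromosome 4 reaches 7 lines lost.

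Among whole chromosomes, 19, 15, 10 and 17 were above the reference and 4 and 7 below it in 7 of 7 lines. Some of these signs rest on values near 0: chromosome 4 was at -0.0046 in F2K, 17 at 0.012 in M1K and 7 at -0.028 in F1K. The mean over lines of the chromosome median log2 ratio was 0.42 ± 0.27 for chromosome 19, 0.40 ± 0.17 for chromosome 15, 0.34 ± 0.17 for chromosome 10 and 0.17 ± 0.08 for chromosome 17 (SD, n = 7). It was -0.32 ± 0.20 for chromosome 4 and -0.15 ± 0.12 for chromosome 7 (SD, n = 7). Each of these 6 had a two-sided exact sign-flip p of 0.0156, the smallest that 7 lines allow, and an adjusted p of 0.0495. Chromosome 8 was at -0.24 ± 0.21 (SD, n = 7), below 0 in 6 of 7 lines, and did not pass (exact sign-flip p = 0.0313, adjusted p = 0.0848). At least 6 chromosomes must have the smallest p for any to pass, so that 1 turning in a single line ends all 6 calls. Only 2 to 5 had it with other centrings, normexp, chromosome means and the authors' deposited value table, where none passed, and those counts of 0 say nothing of single chromosomes. Over 9 settings with all 7 lines, the main one included, the means were 0.26 to 0.50 for chromosome 19, 0.20 to 0.48 for 15, 0.22 to 0.43 for 10, 0.097 to 0.26 for 17, -0.34 to -0.13 for 4 and -0.16 to -0.070 for 7. The smallest exact sign-flip p was kept in 9 settings by chromosomes 10 and 15, in 8 by 19, in 6 by 7 and in 5 by 4 and 17. The test leaves out the spread of the control DNA, since no control sample was hybridised against the reference.

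**Figure D2:**
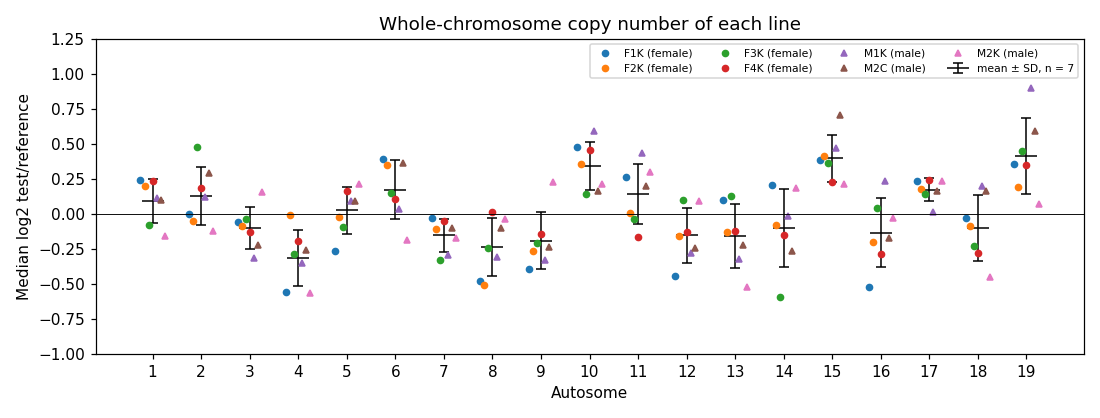
Median log2 test/reference ratio of each autosome in each line (circles, female lines; triangles, male lines), with the mean and SD over 7 lines in black. Chromosomes 10, 15, 17 and 19 are above 0 and chromosomes 4 and 7 below 0 in every line, with chromosome 4 in F2K and 17 in M1K close to 0.

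Bin by bin, 289 bins were higher and 395 lower than the reference in limma's moderated test at an adjusted p of 0.05, of 2392 tested. With peak centring the split was 240 higher and 32 lower, and with normexp background correction 137 and 81. With centring on chromosomes 2, 3, 5 and 7, an alternative chosen after the data were seen, it was 290 and 206. Peak centring moved the zero line of the arrays by 0.25 in F1K, -0.14 in F2K, -0.19 in F3K, -0.15 in F4K, -0.33 in M1K, -0.24 in M2C and 0.21 in M2K on the log2 scale. With scan day as a random block 396 bins were higher and 544 lower; the estimated correlation within days was -0.19, and a negative value raises such counts, so they do not show that calls held within days. Without F1K 261 bins were higher and 144 lower, without M1K 226 and 155, without F2K 252 and 219, and without M2C 249 and 248. For genes, 2578 of 16248 were higher and 2147 lower by the same test. With peak centring 2044 genes were higher and 417 lower, with normexp 976 and 488, and with centring on chromosomes 2, 3, 5 and 7 2797 and 1356. Without F1K 1997 genes were higher and 849 lower, without M1K 2093 and 1042, and without F2K 2044 and 1338. Of 39 named genes past the test, 31 remained so with peak centring, all but Bub3, Cdc20, Cdkn2a, Fat1, Jun, Krtap6-2, Ranbp17 and Rnf43. With normexp 18 remained: besides these, Bicd1, Cacnb1, Cdk2, Cnot6, Cops7b, Dkk1, Erbb3, Gabrp, Iltifb, Krt18, Mdm2, Smarcb1 and Tcf7l2 did not pass. With each gene's own probes Bub3, Cacnb1, Jun, Ranbp17 and Smarcb1 were among those that did not. Rnf43 and Ranbp17 did not pass without F1K, F3K or M1K, Cacnb1 without F3K or M1K, and Rnf43 without M2K. Neighbouring genes share probes and segments, so these counts do not stand for independent events.

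Of the genes followed in any case, Myc and Cdkn2a passed the test over all genes. Myc, a transcription factor that drives growth, lies on chromosome 15 (61818043 to 61818102 on the array) and was at 0.37 ± 0.20 (SD, n = 7; limma adjusted p = 0.000698), gained in 6 of 7 lines. Cdkn2a, which encodes the cell cycle inhibitors p16INK4a and p19ARF, was at -0.92 ± 2.02 (SD, n = 7; limma adjusted p = 0.000413) and called lost in 4 lines, but its mean was -0.16 without F1K and no longer passed. The standard error that limma gave Cdkn2a, 0.21, was drawn toward the spread of other genes, so this p does not reflect its spread between lines. The signal of F1K there was near background, so the mean is only a limit. Cdkn2a also did not pass with peak centring, with normexp, with its own probes alone or without M1K. Trp53 was at -0.15 ± 0.74, Smad4 at -0.13 ± 0.27 and Apc at -0.05 ± 0.26 (SD, n = 7), and none of these passed. Apc, the gatekeeper of Wnt signalling in the colon, was called lost in 2 lines and gained in 0, and its mean was 0.034 with peak centring. Without M2C the mean of Trp53 was 0.11.

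Of the 23 gene lists 1 passed the rotation test, and it was among those of mouse counterparts of human chromosomes or arms often altered in colorectal cancer. This list, of human 1p, an arm often lost, had a median of -0.55 ± 0.20 (SD, n = 7), below 0 in 7 of 7 lines (two-sided permutation p = 0.0015, adjusted p = 0.0345). All 8 of its genes lie on mouse chromosome 4, so that they follow a single region. Counterparts of the arm elsewhere in the mouse genome are not covered by the list. All 8 genes fell, both over all genes tested and adjusted over the list alone. They included Trp73, a relative of p53, at -0.87 ± 0.41, Chd5, a chromatin remodeller, at -0.76 ± 0.38, Runx3, a transcription factor, at -0.55 ± 0.22, and Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, at -0.54 ± 0.23 (SD, n = 7). Ephb2, a receptor tyrosine kinase, was at -0.54 ± 0.20 and Jun at -0.31 ± 0.21 (SD, n = 7). The list did not pass with peak centring, at a median of -0.46 (permutation, adjusted p = 0.379), with normexp background correction, at -0.26 (permutation, adjusted p = 0.140), or with each gene's own probes alone, at -0.52 (permutation, adjusted p = 0.0644). It also did not pass without F1K, F4K or M2C (permutation, adjusted p = 0.0575, 0.0851 and 0.0552).

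The list of human 8q, often gained, had a median of 0.31 ± 0.18 (SD, n = 7), above 0 in 7 of 7 lines, and did not pass (permutation, adjusted p = 0.576). Of its 13 measured genes 7 rose and 1 fell over all genes and adjusted over the list alone. All 7 that rose lie on chromosome 15: besides Myc, they were the adhesion kinase gene Ptk2 at 0.47 ± 0.16, Ywhaz at 0.45 ± 0.22, Tg at 0.44 ± 0.19, the cohesin gene Rad21 at 0.41 ± 0.16, Sdc2 at 0.37 ± 0.14 and Trps1 at 0.36 ± 0.17 (SD, n = 7). Runx1t1, which fell, lies on chromosome 4. The list of human 22q, often lost, stood on the other side, at 0.28 ± 0.12 (SD, n = 7) and above 0 in 7 of 7 lines (permutation p = 0.0233, adjusted p = 0.268). Its genes Ep300, a histone acetyltransferase gene on chromosome 15 at 0.47 ± 0.19, and Smarcb1, a SWI/SNF subunit gene on chromosome 10 at 0.38 ± 0.22 (SD, n = 7), rose, and adjusted over the list alone Nf2 did so too.

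No other list of a human arm passed. The list of human 8p had a median of -0.23 ± 0.17, below 0 in 7 of 7 lines, with 4 of 10 genes lower over all genes and 6 adjusted over the list alone. The lists of human 7 and 20q, often gained, were at 0.14 ± 0.09 and 0.17 ± 0.18, with 1 of 14 and 2 of 13 genes higher over all genes, and 1 and 0 adjusted over the list alone. The list of human 13q, often gained, was at -0.08 ± 0.24, with 3 of 15 genes lower over all genes and 2 adjusted over the list alone. Among arms often lost, 4q was at -0.11 ± 0.17, 5q at -0.09 ± 0.24, 15q at -0.12 ± 0.10, 17p at 0.15 ± 0.24 and 18q at -0.09 ± 0.22 (SD, n = 7). In 4q 1 of 12 genes, Fat1, was lower over all genes and adjusted over the list alone. Its mean was -0.32 ± 0.25 (SD, n = 7), and it did not pass with peak centring, with normexp or without F2K. In 5q, 15q and 18q 0 genes passed either way, and in 17p 2 of 6, Ncor1 and Pafah1b1, were higher both ways. All 7 genes of the 5q list lie on mouse chromosome 18, so counterparts of that arm elsewhere are not covered by the list.

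**Figure D3:**
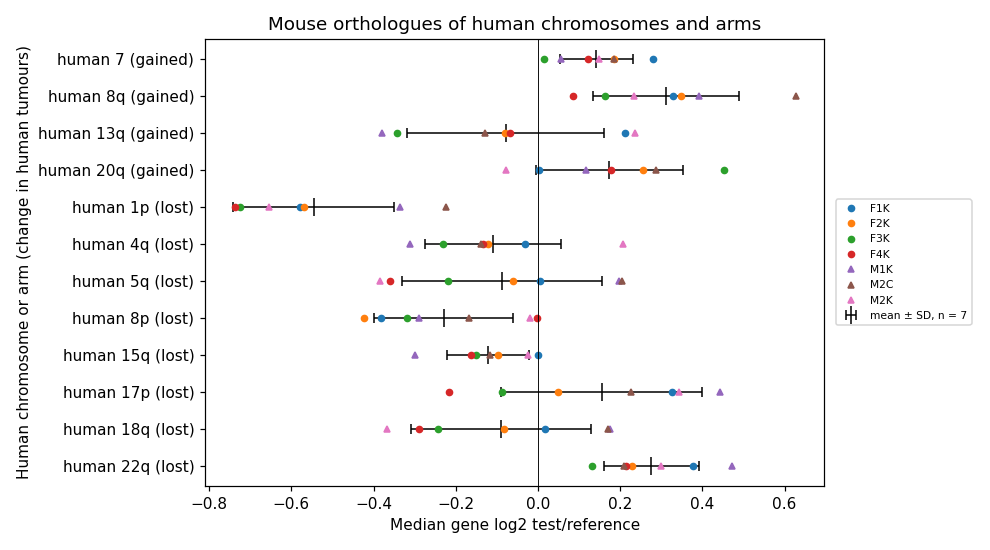
Median log2 test/reference ratio over the genes of each list of a human chromosome or arm, in each line (circles, female lines; triangles, male lines), with the mean and SD over 7 lines in black. With arrays centred on their median, the lists of human 1p and 8p lie below 0 in every line and those of human 7, 8q and 22q above 0 in every line.

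None of the lists of pathways and functions passed the rotation test. Colorectal tumour suppressors were at -0.05 ± 0.14 (SD, n = 7): of 15 measured genes 2 were higher, among them the Wnt transcription factor gene Tcf7l2 at 0.39 ± 0.24 (SD, n = 7), and 2, Arid1a and Cdkn2a, were lower. Colorectal oncogenes were at 0.03 ± 0.10 (SD, n = 7), with 5 of 22 genes higher and 3 lower, and among the former Mdm2, whose product degrades p53, was at 1.54 ± 1.64 and the receptor gene Erbb3 at 0.36 ± 0.19 (SD, n = 7). The standard error that limma gave Mdm2, 0.18, was drawn toward the spread of other genes, so its call does not reflect its spread between lines. Wnt signalling was at 0.07 ± 0.18, with 4 of 15 genes higher, among them the intestinal stem cell receptor gene Lgr5 at 0.44 ± 0.26 and the Wnt inhibitor gene Dkk1 at 0.37 ± 0.24 (SD, n = 7). In these 3 lists the counts were equal adjusted over the list alone.

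The list of TGF-beta and BMP signalling was at -0.11 ± 0.09, with 1 of 14 genes lower and 0 adjusted over the list alone. RAS and PI3K signalling was at -0.01 ± 0.10, with 3 of 20 genes higher and 3 lower, and 3 and 4 adjusted over the list alone. The p53 pathway was at -0.03 ± 0.14, with Mdm2 higher and Trp73 lower of 11 genes, both ways. G1/S cell cycle was at -0.03 ± 0.10, with 2 of 16 genes higher and 3 lower, and 4 and 5 adjusted over the list alone; Cdk2 was at 0.35 ± 0.21 and E2f2, on chromosome 4, at -0.58 ± 0.25 (SD, n = 7). Spindle and mitotic checkpoint was at 0.08 ± 0.10, with 4 of 14 genes higher and 3 lower, and 5 and 4 adjusted over the list alone. Of these, the separase gene Espl1 was at 0.45 ± 0.16, the checkpoint gene Bub3 at -0.40 ± 0.29 and Cdc20, an activator of the anaphase-promoting complex, at -0.34 ± 0.22 (SD, n = 7). Bub3 and Cdc20 did not pass with peak centring or normexp, nor Bub3 with its own probes. Telomere maintenance was at 0.06 ± 0.09, with 1 of 7 genes, Tert, lower, and mismatch and excision repair at 0.03 ± 0.10, with 1 of 10 higher and 1 lower, the counts being equal adjusted over the list alone. Colon epithelial identity was at 0.16 ± 0.09 (SD, n = 7), above 0 in 7 of 7 lines (permutation, adjusted p = 0.482), with 3 of 14 genes higher both ways: Lgr5 and the keratin genes Krt8, at 0.47 ± 0.21, and Krt18, at 0.46 ± 0.20 (SD, n = 7).

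Focal high-level events were found in 5 of 7 lines, 10 gains and 3 losses of at most 5 Mb. The deepest was a deletion on chromosome 4 from 88353779 to 89228030 in F1K, with a mean log2 ratio of -5.57 over 92 probes, and it held Cdkn2a. The test signal of 95.7% of these probes was not well above background in F1K, with a median of 2.49 against 126 on autosomes and 2.57 on Y, so the ratio is a limit. Mdm2 was amplified in F3K, within a segment of chromosome 10 from 116457236 to 117214233 at 3.87 over 89 probes, and in M2K, from 117034000 to 118648826 at 3.81 over 122 probes. The neighbouring segment in F3K, from 117218984 to 118619244, was at 1.80 and had Iltifb at its middle. In M2C a segment of chromosome 11 from 69117937 to 69559255 was at -1.72 over 72 probes and held Trp53, the p53 gene, whose own value there was -1.71. In the 6 other lines Trp53 lay between -0.24 and 0.43.

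F3K held 6 of the 10 focal gains, where the segment with Mdm2 and its neighbour on chromosome 10 count as separate gains. On chromosome 11 these were a segment from 84297074 to 88954193 at 1.11 with Rnf43, a ubiquitin ligase gene that dampens Wnt signalling, another from 32416909 to 33745856 at 1.06 with Ranbp17 at its middle, and another from 97593482 to 98201071 with Cacnb1 at its middle. On chromosome 12 the segment from 52377022 to 53383013 was at 1.09, with Heatr5a at its middle. F1K had a gain on chromosome 3 from 121224043 to 122250862 at 1.04 with Abca4 at its middle. The other 3 events were the smallest by log2 ratio times probes, of 8 to 19 probes: 2 gains in M2K and 1 loss in F4K. With a segmentation penalty factor of 20 there were 5 gains and 2 losses, and with normexp 5 gains and 10 losses.

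Recurrent regions without a gene of the lists were represented by the annotated gene at their strongest bin. The region of chromosome 1 from 94000001 to 98000000, of 4 bins and gained in up to 5 lines, had no matched gene there. On chromosome 1 these were Cops7b at 0.28 ± 0.23, Lpgat1 at 0.17 ± 0.18, Aff3 at 0.16 ± 0.25 and Erbb4 at 0.11 ± 0.28 (SD, n = 7), of which Cops7b passed the test over all genes. On chromosomes 6 and 11 they were Bicd1 at 0.32 ± 0.24, Gabrp at 0.30 ± 0.43 and Cnot6 at 0.26 ± 0.15, and on chromosome 16 Krtap6-2 at -0.37 ± 0.32 (SD, n = 7), all of which passed. Each was gained in 4 lines, except Krtap6-2, which was lost in 5. Cops7b, Gabrp and Cnot6 did not pass without F1K, Gabrp and Cnot6 without M1K, and Cnot6 and Cops7b without M2C. Gabrp lies in a focal gain of F3K, at 1.16 there, and without F3K its mean was 0.15 and did not pass. Bicd1, Gabrp, Cnot6, Cops7b and Krtap6-2 did not pass with normexp, Krtap6-2 with peak centring, Cops7b with the authors' deposited value table, and Cops7b and Gabrp with their own probes alone.

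Female and male lines did not differ in any autosomal bin in limma's test at an adjusted p of 0.05, and 97 bins of 2392 had an unadjusted p under 0.05. With scan day as a block 1 bin passed. The X median was 0.03 ± 0.28 (SD, n = 4) in female and 0.10 ± 0.06 (SD, n = 3) in male lines, a female minus male difference of -0.08 (two-sided exact permutation p = 0.657). The X signal of the reference went with the sex of the line, so this test does not check the sex labels. With scan day as a block the X difference was -0.00, within 1 day with lines of both sexes it was -0.25 and within the other 0.33. The Y median was 0.33 ± 0.53 (SD, n = 4) in female and -1.81 ± 2.42 (SD, n = 3) in male lines, a difference of 2.14 (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted p = 0.0571 over both chromosomes). The Y difference was 2.99 with scan day as a block, 4.62 and 0.81 within the same days, and 0.76 without M2K. On the arrays of female lines both channels carried little Y signal, so the ratio there has no meaning as a copy number. Among male lines the Y median was -0.19 in M2C, -0.66 in M1K and -4.59 in M2K, where the Y signal of the test DNA was 2.05% of the autosomal signal against 33.1% in M1K and 40.8% in M2C. That is at the level of the female lines, 2.04% to 7.78%, and 48.2% of the Y probes of M2K were not well above background, so -4.59, the male mean and the difference are limits.

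The profiles of the lines resembled each other to different degrees. Over bins, Pearson's r was highest between M1K and M2C, at 0.70, and the 15 pairs without M2K lay between 0.30 and 0.70. M2K had an r of 0.12 to 0.25 with the 6 other lines. M2C and M2K, which share a code in their titles, had an r of 0.17, rank 19 of 21 pairs. Bins are not independent, so no p is given. Arrays of the same platform can share technical deviations, which raise r. Deviations of bins from their segments had an r of -0.45 to 0.64 over the 21 pairs, with a median of 0.28 and 4 pairs below 0. Their mean covariance was 0.000909, which is 2.35% of the 0.0387 of the bins themselves. Shared technical deviations wide enough to form segments are not part of it, so this share sets no limit on those.

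No relation between the altered share of the genome and passage passed the test. Pearson's r was -0.56 over 7 lines (exact permutation p = 0.195) and Spearman's rho -0.32 (exact permutation p = 0.477). M2C lay farthest from the median passage, and F1K and F2K were next and tied. Over the 5 other lines r was 0.08 without M2C and F1K and -0.48 without M2C and F2K. With scan day as a block, to which 5 lines contribute, r was 0.21 (exact permutation p = 0.917, where 12 orders allow no less than 0.0833). Over the alternatives r ran from -0.73 to 0.27, so its sign is not settled.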

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

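The test of M2K by its X signal, the count over splits of the lines and the values within scan days were chosen only after related results had been seen.

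Among the 4 female lines, 1 line stood apart from the other 3 in 6 of 94 values examined by Dixon's test, and chance gives about 1 in 20. Some genes were among these values because of a focal event in 1 line, so that rate does not apply to them. Cdkn2a was at -5.46 in F1K and between -0.04 and 0.15 in the others. Mdm2 was at 3.99 in F3K, and Abca4 at 1.03 in F1K; these 3 lie in focal events described above. The value of Cdkn2a is a limit, since the signal was near background. Chromosome 1 had a median of -0.077 in F3K against 0.20 to 0.24 in the others, and Aff3, on the same chromosome, was at -0.17 in F3K. Ptk2 was at 0.29 in F4K, against 0.47 to 0.48.

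Of 92 values compared between female and male lines, 2 differed by an exact permutation test, and the smallest adjusted p over the 92 was 0.657 (exact permutation). Chromosome 13 differed by 0.35, with means of -0.01 in female and -0.36 in male lines (exact permutation p = 0.0286); with scan day as a block the difference was 0.39, and within the 2 days with lines of both sexes 0.52 and 0.20. The Y median differed by 2.14 on the log2 scale (exact permutation p = 0.0286), and the female arrays have little Y signal in either channel. The value is a limit, since M2K was at background.

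The test DNA of M2K lacked most Y signal. A female line under a male label is argued against by its X signal, 60.1% of the autosomal signal, where the 4 female lines had 81.5% to 127%, unless such a line had also lost an X. Loss of the Y chromosome in culture may account for it; no test here bears on when it was lost, and no biological explanation was tested.

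The count of autosomal bins that differed between female and male lines was 0, and 35 of 35 splits of the lines gave at least as many, with a highest count of 16 in another split, F1K, F4K, M1K and M2C against the rest. With a real count of 0 every split gives as many, so the splits decide nothing about chance. In simulated data the test recovered 0% of bins shifted by 0.3 at this number of lines.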

How the results depend on the processing

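The GC correction, the centrings on chromosomes 2, 3, 5 and 7 and on the chromosomes without recurrent bins, and the values within scan days, with passage against scan day as a block, were chosen only after the data were seen. The set of chromosomes 2, 3, 5 and 7 was picked by hand, before a rule was set that gave 2, 3, 5, 7, 14, 17 and 18. Chromosomes 7 and 17 also passed the sign-flip test in the main setting, so these sets are not neutral for them. Of the alternatives for results that answer a comparison, 181 kept direction and side of the threshold or stayed within the limits set for a change, 85 moved beyond them, 10 no longer passed and 6 reversed. For other values these were 1318 kept, 148 no longer passing and 30 reversed. Between 0.129% and 0.534% of spots were not well above background or saturated, but normexp moved the counts of recurrent bins more than leaving out any line did. That setting started from the raw mean signals, so it also left out the software's detrending. It used an offset of 50, and an offset added to both channels compresses log2 ratios, most where signals are low. The median autosomal test signal in the main setting ran from 126 in F1K to 720 in M2K. Counts at a fixed call threshold can then fall by construction, so the normexp counts do not measure the effect of background alone. Causes were not tested except where stated.

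The mean gained share was 35.3% with peak centring, 13.9% with normexp, 35.8% at a call threshold of 0.15 and 13.8% at 0.3; the lost share was 9.01% with normexp, 37.1% at 0.15 and 14.8% at 0.3. Bins gained in at least 4 lines numbered 876 with peak centring, 49 with normexp, 824 at 0.15, 233 at 0.3, and by construction 788 for at least 3 lines, 220 for at least 5 and 879 with 500 kb bins. Bins lost numbered 34, 36, 913 and 116 in these settings, 141 for at least 5 lines, 1032 with 500 kb bins, 277 with M2C and M2K averaged and 313 with centring on chromosomes without recurrent bins. Bins gained in all 7 lines numbered 2 with peak centring, 0 with normexp, 90 at 0.15, 0 at 0.3, 3 with centring on chromosomes without recurrent bins and 0 on chromosomes 2, 3, 5 and 7; bins lost in all 7 numbered 0 with peak centring, 2 with normexp, 11 with the deposited value table and 0 at 0.3. Leaving out each line gave 220 to 397 gained and 150 to 437 lost bins in at least 4 lines. The threshold stayed at 4 lines with fewer profiles present, here and with M2C and M2K averaged, which lowers such counts by construction.

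Of chromosomes, 0 passed the sign-flip test with peak centring, 0 with normexp, 0 with the deposited value table, 0 with chromosome means, 0 with M2C and M2K averaged, 0 with centring on chromosomes without recurrent bins and 0 on chromosomes 2, 3, 5 and 7. It was 0 to 0 when each line was left out: 6 lines cannot give an exact sign-flip p under 0.0313, so this and the averaging say nothing about stability. With 7 lines 6 chromosomes must have the smallest p for any to pass, so the other counts of 0 say nothing of single chromosomes. Leaving out each line gave chromosome 5 a mean of -0.0066, without M2K, to 0.073. In limma's test 137 bins were higher and 81 lower with normexp, 577 and 755 with 500 kb bins by construction, and 32 lower with peak centring and 206 with centring on chromosomes 2, 3, 5 and 7. Leaving out each line gave 144 to 483 lower bins. For genes, 976 were higher and 488 lower with normexp, 417 lower with peak centring and 1356 with centring on chromosomes 2, 3, 5 and 7; leaving out each line gave 849 to 3130.

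Lists past the rotation test numbered 0 with peak centring, 0 with normexp and 0 with own probes, and 0 to 1 when each line was left out. The adjusted permutation p of human 1p ranged from 0.0115 to 0.379 over all settings. With peak centring the sign turned for 13q (0.0049), tumour suppressors (0.032), RAS and PI3K (0.077), p53 pathway (0.053), G1/S (0.057) and Apc (0.034). With 1 value per chromosome it turned for 15q (0.0053), RAS and PI3K (0.019), p53 pathway (0.047), G1/S (0.040) and mismatch repair (-0.048); with list means for RAS and PI3K (0.040), p53 pathway (0.0065) and mismatch repair (-0.010). It also turned with own probes for oncogenes (-0.028) and G1/S (0.015), with bright probes for G1/S (0.0027), with normexp for telomere maintenance (-0.0048) and Abca4 (-0.011), and for RAS and PI3K with centring on chromosomes without recurrent bins (0.0045) and on 2, 3, 5 and 7 (0.014). Leaving out each line gave RAS and PI3K -0.035 to 0.0093, Apc -0.096 to 0.0063 and Trp53 -0.24 to 0.11. Abca4 ranged from -0.13, without F1K, to 0.10 and Heatr5a from -0.12, without F3K, to 0.11; these are the lines with their focal gains.

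The X difference was 0.12 with normexp, 0.33 within scan day 3 and -0.19 to 0.032 when each line was left out. The Y difference was 0.63 with normexp, 4.62 within scan day 2, 1.87 with M2C and M2K averaged and 0.76 to 2.96 when each line was left out, where the averaging and each left-out line leave too few splits to pass. Autosomal bins that differed between female and male lines numbered 1 with normexp, 1 with scan day as a block and 0 to 1 when each line was left out, by limma. The correlation with passage was 0.268 with normexp, 0.159 at a call threshold of 0.15 and 0.208 with scan day as a block. Focal gains numbered 5 with normexp and 5 with a penalty factor of 20; focal losses numbered 10 with normexp, 6 with the deposited value table and 6 at a focal threshold of 0.8.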

Other observations

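The tests of focal placement, GC content, the reference and dye orientation were chosen only after related results had been seen; the test by segment means was set out before its result was seen.

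The 2 mitochondrial probes, which no comparison used, were below the reference in 6 of 7 lines, with a mean log2 ratio of -0.70 ± 0.78 (SD, n = 7). M2K was at -2.25, M1K at -0.86, F2K at -0.78, M2C at -0.77, F3K at -0.17, F1K at -0.05 and F4K at 0.00. The signal of these probes in the reference, which also sets the ratio, ran from 2881% of the autosomal signal on the array of F1K to 11493% on that of M2K. In the test DNA it was 2427% in M2K, 2788% in F1K, 3041% in F4K, 3134% in F2K, 3318% in M1K, 4621% in M2C and 5106% in F3K, so the ratios do not rank the lines by their mitochondrial DNA.

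Focal events fell on genes of the p53 pathway list in 3 of the 5 lines that had an autosomal focal event: Mdm2 in F3K and M2K, and Trp53 in M2C. With the focal segments of each line rotated along the autosomes, 0.066 lines did so on average and 2 at most in 10000 draws (rotation permutation p = 0.0001, the smallest the draws can give), which argues against random placement of the focal segments. The list was fixed before the data were examined, but the test was chosen after the focal segments and their genes had been seen, so that its p overstates the evidence. Cdkn2a, whose product p19ARF inhibits Mdm2, was deleted in F1K and is not on that list. A hypothesis is that single focal events may have reduced p53 function in these 4 lines; this was not tested, since it needs p53 target expression after DNA damage and the Trp53 sequence, above all in F2K, F4K and M1K, which had no such event.

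The recurrent gains and losses may be a property of the arrays instead of the lines, since in 17 of 21 pairs of arrays bins deviated from their segments with an r above 0. The mean covariance of these deviations was 0.000909 against 0.0387 for the bins themselves. It leaves out deviations wide enough to form segments, so it does not decide how much of the recurrence is technical. With the GC trend removed, the rotation test still passed for gains (permutation p = 0.0061, 331 bins) and for losses (permutation p = 0.0001, 518 bins), which argues against the trend as the whole cause. Altered copy number in the reference stays open: the median range over the 4 female arrays was 0.43 in recurrent and 0.43 in other bins, so it reflects the lines' own changes and decides nothing. The X signal of the reference differed between arrays of female and male lines. A change in a single reference DNA could therefore not by itself give bins altered in all 7 lines, but one shared by these DNAs could. The zero line stays open too: in at least 4 lines gains passed with all 3 other centrings (permutation p = 0.0001, 0.0003 and 0.0028) and losses with 2 (permutation p = 0.0006 and 0.0057) but not with peak centring (permutation p = 0.0684, 34 bins), while the count of bins gained in all 7 lines, 30, was 2, 3 and 0 with these centrings and that of bins lost in all 7 lines, 24, was 0, 24 and 35. No biological explanation was tested.

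M2K resembled the other lines least. Exchanged dyes would turn its sign, but its r with the 6 other lines was above 0 in all, with a median of 0.20. Probe noise would be removed by segment means, but with these the median r was 0.176, below the lowest of the pairs without M2K, 0.29. Bins already average at least 10 probes, and over all pairs the median r was 0.473 with bins and 0.474 with segment means. This test therefore decides little about noise. The spread of differences between neighbouring probes was 0.256 in M2K, within the range from 0.132 in M1K to 0.421 in F3K. A different course of M2K in culture, or a different animal of origin than M2C, may account for this, and neither was tested.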
